A study of Mus musculus with 8 samples.

How the data were processed

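Cultured smooth muscle cells from the aortas of 4 mice were each given 2 adenoviruses, Ad-PL as the control and Ad-Cre to make the NFAT5 knockout, so that 4 Ad-PL and 4 Ad-Cre samples form 4 pairs. The cells met the virus for 18 hours and were kept for a further 48 hours before total RNA was taken, per the labels' protocols. Biotin-labelled cRNA was hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds log2 expression values for 25428 probe sets in 8 samples, made with RMA (background correction, quantile normalization and summary of the probes of a probe set), per the submitters' processing notes. Neither the RMA version nor the array annotation is stated. Sample medians of the deposited log2 values ran from 4.18 to 4.20, and no value was missing. For arrays no depth exists, and the 4 mice limit the precision.

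Each probe set carries an Entrez gene ID, and 24705 of the 25428 were paired with 1 gene symbol in the platform annotation. The other 723 probe sets are unnamed here, and none had several symbols. Of the named probe sets, 24673 had an Entrez ID in the NCBI gene table of the GRCm38.p6 assembly, which was used only for names and for which genes neighbour each other, and 0 of these carried a different symbol there. Where 1 symbol had 2 probe sets the one with the higher mean was kept, which left 24704 genes. No filter on dim probe sets was applied in the values reported.

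The mouse numbers in the sample descriptions pair the samples, since a pair comes from the same animal. The pairing was checked on the values. For every probe set the sum of the Ad-PL and the Ad-Cre value was nearly identical in all 4 mice (median range 0.000763, largest range 0.00383 on the log2 scale). Deviations from the group means had a correlation of -1.00 between the samples of a mouse, and of 0.278 to 0.400 between samples of different mice and different groups. The difference between mice had thus been taken out of the values before deposit, a step that no label records. With it gone, the 8 samples carry only 4 independent differences, so a fit without the mouse counts 6 residual degrees of freedom where the values hold 3.

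Before the data were examined, the gene lists, the rule for named genes, the tests and most alternatives had been written down, with a fit without the mouse as the main design. Because the values turned out to lack the mouse difference, the results below come from the second fit written down then, with the mouse as a block, a choice made after the values were seen. The fit as first planned is given as an alternative for the counts of genes, for Nfat5 and for the lists. Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment over the 24704 genes and an adjusted p threshold of 0.05. Errors are the SD of the 4 within-mouse differences, and intervals are 95% intervals from the limma fit.

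A total of 33 gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They were NFAT family, tonicity response, contractile smooth muscle, extracellular matrix, matrix proteases, adhesion and migration, G1/S replication, G2/M mitosis, p53 targets, interferon response, NF-kB and chemokines, cholesterol synthesis, unfolded protein and amino acid stress, heat shock, TGF-beta and YAP targets, Notch signalling, growth factors, calcium handling and ion channels, glycolysis and hypoxia, lysosome and autophagy, Nrf2 targets, and ribosome biogenesis with MYC targets. A further 8 lists held markers of endothelium, leukocytes, adventitial fibroblasts, cartilage and bone, fat, nerve, striated muscle, and mesothelium or epithelium. The last 3 tracked sample quality with ribosomal protein genes, immediate-early genes and replication-dependent histones. Histone symbols were matched through older symbols for all 29 measured members. Each list was also tested with camera at an estimated correlation and with fry. Fry was run in its directional form, reported unless stated, and in its mixed form, which asks for differences in either direction. List members were also counted adjusted over the list alone.

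The genes named are Nfat5, the 8 highest and 8 lowest differences among genes past the threshold in the fit without the block that had the same sign in 4 of 4 mice, and up to 4 members per list ordered by p in that fit. The same rule in the fit with the block named no gene, since none passed. Predicted genes, small RNA genes and olfactory or vomeronasal receptors were counted and not named. Genes named outside this rule are marked as such.

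The tests were tried on simulated data for the comparison of Ad-Cre with Ad-PL. The simulation took the real levels of all 24704 genes, and the mouse difference was removed as in the deposited values. Its spreads were those moderated by eBayes, which are more even over genes than the real ones, and genes were drawn independently. The shares recovered may therefore be higher than the real data allow. In 20 simulated runs with no change, the fit with the block called a median of 0 genes and at most 2, and the fit without it a median of 368 (288 to 435). With 200 genes changed 1.5-fold, the fit with the block recovered 29.0% of them, and 54.5% with the trend and robust settings of eBayes. The fit without the block recovered 88.0% and called 530 unchanged genes. At 2-fold the fit with the block recovered 97.0% of 200 changed genes, and at 4-fold 100%.

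The alternatives were no block, a random block (duplicateCorrelation), quantile normalization, median centring, filters at the 25th and 50th percentile of level, the mean of the probe sets of a gene, all probe sets, eBayes with trend and robust, array weights, other thresholds, and leaving out each mouse or sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.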

Results

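Gene expression was profiled on Affymetrix arrays in cultured vascular smooth muscle cells (VSMCs) grown from the aortas of 4 mice. Cells of each mouse received the adenovirus Ad-PL (control) or Ad-Cre (NFAT5 knockout), which gave 4 samples per group in 4 pairs. The study concerns NFAT5, also named TonEBP, a transcription factor known from the response to hypertonic stress, and its genetic ablation in smooth muscle during remodelling of arteries. The comparison asks which transcripts differ between isolated VSMCs given Ad-Cre, meant to remove the gene, and those given Ad-PL. All values are log2 RMA expression from which the difference between mice had already been removed, and every difference below is Ad-Cre minus Ad-PL within a mouse.

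Nfat5 was lower in Ad-Cre cells of 4 of 4 mice. Its single probe set (54446_at, Entrez gene 54446) averaged 7.95 in Ad-PL and 7.44 in Ad-Cre samples, a difference of -0.52 ± 0.09 (SD, n = 4 mice). This was a level 30.1% lower (95% confidence interval 19.8% to 39.1%). The differences in the 4 mice were -0.41, -0.62, -0.48 and -0.56. Nfat5 passed the threshold adjusted over the list alone, that of the 6 genes in the NFAT family list, and ranked 25th of 24704 genes by p. Over all genes its adjusted p was 0.425 in limma with the mouse as a block, 0.00859 with the trend and robust settings of eBayes, and 0.00169 without the block. Leaving out mouse 2 ended the call with trend and robust set (adjusted p = 0.0583). The labels state neither which part of the gene was deleted, nor whether the cells carry a form of it that Cre can cut, nor what Ad-PL carries, so the probe set may read a transcript that is still made.

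Among the genes named, Sprr1a had the largest difference. This gene for a small proline-rich protein, best known from the cornified envelope of epidermis, averaged 8.16 in Ad-PL and 6.76 in Ad-Cre cells, a difference of -1.40 ± 0.18 (SD, n = 4 mice) or 2.64-fold. The interferon-inducible gene Ifi209 was 2.28-fold lower (-1.19 ± 0.30), with a low array signal (mean 4.37 in Ad-PL and 3.19 in Ad-Cre). Igfbp5, which binds insulin-like growth factors, was 1.87-fold lower (-0.91 ± 0.33), as was Prrg4, a membrane protein with a Gla domain (-0.90 ± 0.15). Dio2, the deiodinase that activates thyroid hormone, differed by -0.89 ± 0.47, and the peptide hormone gene Cck by -0.80 ± 0.31. Of 2 further genes of the cornified envelope region, Lce3d differed by -0.86 ± 0.41 and Crct1 by -0.81 ± 0.67. Each of these 8 genes was lower in 4 of 4 mice, which the rule for named genes required, and Crct1 differed by only -0.03 in mouse 4.

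The 8 highest differences were in genes with low array signal, with Ad-PL means between 2.03 for Ighv1-19 and 4.39 for Speer4cos. Cldn34c2, of the claudin family, was 2.08-fold higher (1.06 ± 0.64, SD, n = 4 mice). Rsf1os2, a noncoding transcript, had the tightest spread of them, with 0.88 ± 0.12. The others were Speer4cos at 0.87 ± 0.47, the protocadherin Pcdha10 at 0.82 ± 0.56, the glucuronosyltransferase Ugt1a6b at 0.81 ± 0.47, Frg2f8 at 0.80 ± 0.37, the proton pump subunit Atp6v1g3 at 0.75 ± 0.38 and Ighv1-19 at 0.72 ± 0.26. All 8 were higher in 4 of 4 mice, which the rule for named genes required.

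**Figure D1:**
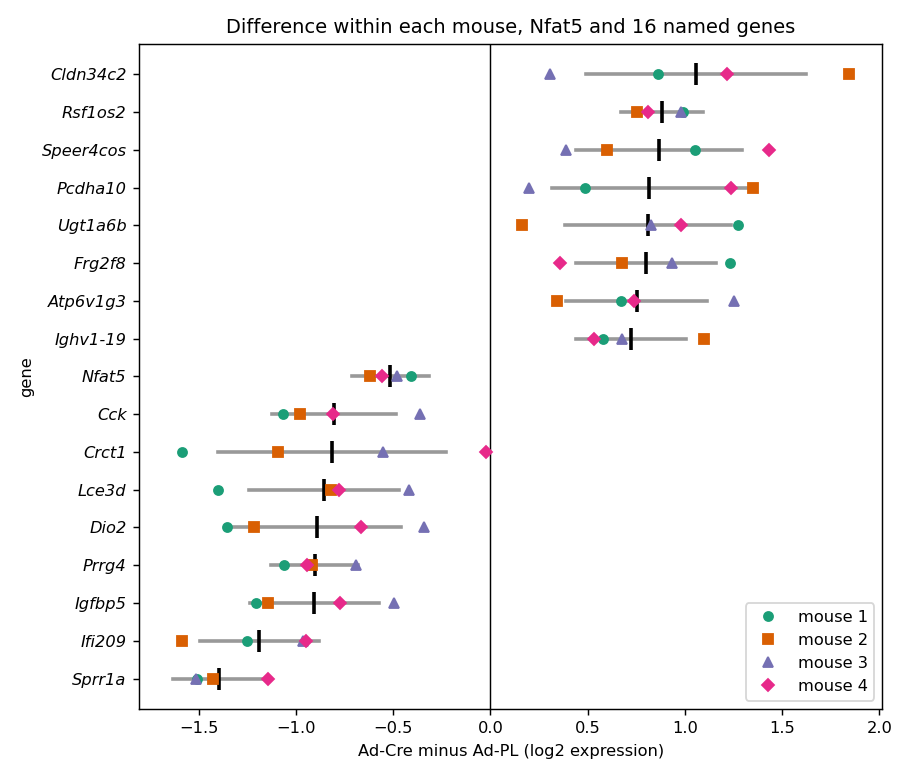
Within-mouse differences, Ad-Cre minus Ad-PL on the log2 scale, of Nfat5 and the 8 highest and 8 lowest genes named by the rule, which leaves out predicted genes, with 1 symbol per mouse, a vertical tick for the mean of 4 mice and a grey line for the 95% confidence interval of the limma fit. The 4 Nfat5 values lay between -0.62 and -0.41, and those of Sprr1a between -1.51 and -1.14.

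Across the 24704 genes, 0 passed an adjusted p of 0.05 in limma with the mouse as a block, and Sprr1a came closest (adjusted p = 0.104). At an unadjusted p under 0.05 there were 2291 genes (9.27%, where chance gives 5%), of which 1031 were higher and 1260 lower in Ad-Cre cells. With trend and robust set in eBayes, 131 genes passed, 45 higher and 86 lower, and all 131 had the same sign in 4 of 4 mice. That count was 37, 18, 45 and 108 without mouse 1, 2, 3 and 4, with 31, 13, 41 and 77 of the 131 among them. The 131 included Nfat5, Sprr1a (adjusted p = 8.56e-06), Prrg4 (0.00705), Ifi209, Igfbp5, Dio2, Lce3d, Cck, Rsf1os2, Speer4cos and Ighv1-19. Without the block, the design first planned, 2183 genes passed (976 higher, 1207 lower). That number overstates the evidence, since removal of the mouse difference made the residual spread too small. Differences were modest in size: 151 genes differed by at least 1.5-fold on average (93 higher, 58 lower) and 7 by at least 2-fold. In 4 of 4 mice 2176 genes (8.81%) were higher and 2386 (9.66%) lower, where chance gives 6.25% each.

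Genes of mitosis were lower together in Ad-Cre cells. All 30 measured members of the mitosis list had a mean difference below 0, 19 of them were lower in 4 of 4 mice, and the list median was -0.35 (-0.43, -0.43, -0.57 and -0.11 in the 4 mice). As a list they were lower than other genes by camera (adjusted p = 4.85e-19, and adjusted p = 0.326 with an estimated correlation), and did not pass in fry (adjusted p = 0.0622). The immediate-early genes, tracked as a sign of handling and serum response, were lower beside the mitosis, interferon and contractile lists (median -0.09, camera adjusted p = 0.00756, and adjusted p = 0.320 with an estimated correlation). Adjusted over the mitosis list alone, 17 members passed, all lower. They included the spindle kinase Aurka (-0.61 ± 0.15, SD, n = 4 mice), Ect2, which directs cytokinesis (-0.50 ± 0.10), the mitotic cyclin Ccnb2 (-0.50 ± 0.12) and the kinetochore motor Cenpe (-0.46 ± 0.06). The 29 genes of replication and the G1/S transition did not pass as a list (median -0.07, adjusted p = 0.0692). Of them 1 passed adjusted over the list alone, the ribonucleotide reductase subunit Rrm2 (-0.49 ± 0.10), which was lower in 4 of 4 mice. The helicase subunit Mcm6 differed by -0.35 ± 0.12.

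Interferon-stimulated genes were the second large group on the lower side. Of 38 measured members 36 had a mean below 0 and 24 were lower in 4 of 4 mice, with a list median of -0.23 and mouse medians between -0.34 and -0.18. The list was lower by camera (adjusted p = 5.31e-16, and adjusted p = 0.320 with an estimated correlation). Adjusted over the list alone 15 members passed, all lower. Among them were Oasl1 (-0.63 ± 0.08, SD, n = 4 mice), Oas2 of the antiviral oligoadenylate synthetases (-0.48 ± 0.13), the immunity-related GTPase Igtp (-0.46 ± 0.09) and the antiviral GTPase Mx2 (-0.33 ± 0.05). The 36 genes of NF-kB signalling and chemokines went both ways and did not pass in camera as a list (median -0.01, adjusted p = 0.863). They passed in mixed fry, for differences in either direction (adjusted p = 0.00883). With trend and robust set 3 members of this list passed: the prostaglandin synthase Ptgs2 was lower (-0.34 ± 0.05), and the chemokines Ccl7 (0.36 ± 0.12) and Cxcl12 (0.22 ± 0.05) were higher.

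The contractile programme of smooth muscle was lower by a small and even amount. The 25 genes had a median of -0.15, with mouse medians between -0.16 and -0.12, and 24 of them had a mean below 0. Camera placed the list lower (adjusted p = 1.03e-06, and adjusted p = 0.314 with an estimated correlation). The estimated correlation was -0.0012 for this list, below the preset 0.01, and 0.42 for mitosis. Correlation between genes therefore cannot account for the larger p of the contractile list. The cholesterol, immediate-early, lysosome and ribosome biogenesis lists also had estimates below the preset. Adjusted over the contractile list alone 3 passed: the smooth muscle gamma actin Actg2 (-0.58 ± 0.14, SD, n = 4 mice), calponin Cnn1 (-0.43 ± 0.11) and Myocd, the coactivator that drives the programme (-0.41 ± 0.17). Actg2 and Cnn1 also passed with trend and robust set. Myocd, with a low array signal (Ad-PL mean 4.08), did not (adjusted p = 0.298). The myosin light chain Myl9 differed by -0.25 ± 0.06 and passed with trend and robust set (adjusted p = 0.0144). Each of these 4 genes was lower in 4 of 4 mice.

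Genes known as NFAT5-dependent under hypertonic stress were lower as a list. The 15 measured tonicity genes had a median of -0.18 (camera adjusted p = 0.000447, and adjusted p = 0.384 with an estimated correlation) and did not pass in fry (adjusted p = 0.0622). Of them 8 were lower and 1 higher in 4 of 4 mice. Adjusted over the list alone 2 passed, both lower: the chaperone Hspa4l (-0.35 ± 0.05, SD, n = 4 mice) and the inositol transporter Slc5a3 (-0.49 ± 0.24). The taurine transporter Slc6a6, at -0.27 ± 0.05, passed with trend and robust set (adjusted p = 0.0299). The glucose transporter Slc2a4, with a low array signal (Ad-PL mean 3.96), differed by -0.33 ± 0.20. Of the 5 other genes in the NFAT family list 4 had a mean below 0 and 1 above, each by less than its SD over mice. The list holds Nfatc2ip, which codes for an interacting protein and is not itself an NFAT factor. The list did not pass in camera (median -0.02, adjusted p = 0.423) and, with Nfat5 in it, was lower by fry (adjusted p = 0.0392), with -0.18 ± 0.35 for Nfatc2ip, 0.10 ± 0.21 for Nfatc4 and -0.02 ± 0.32 for Nfatc2.

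Lists of lower members with smaller medians also passed. The 20 genes of cholesterol synthesis had a median of -0.13 (adjusted p = 0.00683, and adjusted p = 0.320 with an estimated correlation), 0 passed adjusted over the list alone, and the synthase Hmgcs1 stood at -0.30 ± 0.09 (SD, n = 4 mice) and the demethylase Cyp51 at -0.39 ± 0.29. The 27 immediate-early genes had a median of -0.09 (adjusted p = 0.00756, and adjusted p = 0.320 with an estimated correlation). Adjusted over the list alone 2 of them passed, both lower, and Dusp1 differed by -0.42 ± 0.12 and Nr4a1 by -0.60 ± 0.27. The 36 genes of adhesion and migration had a median of -0.08 (adjusted p = 0.00829, and adjusted p = 0.624 with an estimated correlation). Of these the integrin Itga4 passed adjusted over the list alone (-0.52 ± 0.08), while cortactin, Cttn, lay on the other side (0.32 ± 0.05) and passed with trend and robust set (adjusted p = 0.00859). The 25 genes of ribosome biogenesis had a median of -0.05 (adjusted p = 0.0441, and adjusted p = 0.326 with an estimated correlation), with -0.20 ± 0.04 for Mybbp1a and -0.17 ± 0.09 for Myc itself. The call of the ribosome biogenesis list was lost when any 1 mouse was left out.

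Genes of the oxidative stress response and of lysosomes were higher as lists. The 21 Nrf2 targets had a median of 0.09 (adjusted p = 0.000337, and adjusted p = 0.580 with an estimated correlation), with 9 members higher in 4 of 4 mice and none lower in all. Adjusted over the list alone 2 passed, the metallothionein Mt1 (0.64 ± 0.24, SD, n = 4 mice) and the glutathione transferase Gsta4 (0.57 ± 0.20). A second metallothionein, Mt2, was at 0.27 ± 0.13. The 27 genes of lysosome and autophagy had a median of 0.05 (adjusted p = 0.0441, and adjusted p = 0.326 with an estimated correlation). The call of this list was lost when any 1 mouse was left out. None of its genes passed adjusted over the list alone, and the lysosomal enzyme Hexa, at 0.31 ± 0.09, passed with trend and robust set (adjusted p = 0.0120).

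**Figure D2:**
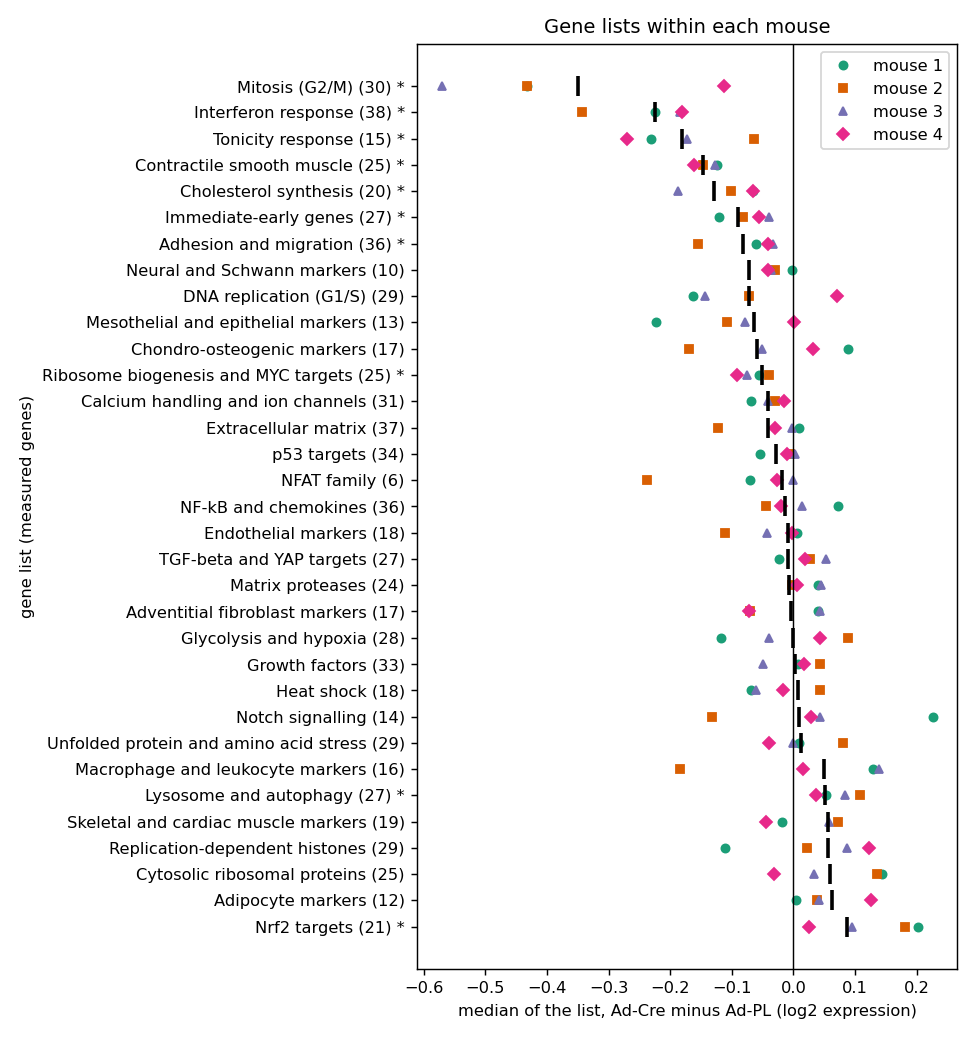
Median difference of each gene list, Ad-Cre minus Ad-PL on the log2 scale, with 1 symbol per mouse, a vertical tick for the median of the mean differences, the number of measured genes in brackets and an asterisk where camera with the preset correlation gave an adjusted p under 0.05. All 10 lists with an asterisk had their 4 mouse medians on one side of 0, and 0 of them passed with an estimated correlation.

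Matrix genes did not shift in one direction as a list. The 37 extracellular matrix genes had a median of -0.04 (camera adjusted p = 0.241). They passed in mixed fry, for differences in either direction (adjusted p = 0.00883). Tenascin C, Tnc, was lower (-0.43 ± 0.13, SD, n = 4 mice) and decorin, Dcn, higher (0.24 ± 0.11) in 4 of 4 mice, and both passed with trend and robust set (adjusted p = 0.00859 and 0.0378). The 24 matrix proteases and inhibitors had a median of -0.0079 (adjusted p = 0.880), with -0.36 ± 0.22 for the urokinase gene Plau. The 33 growth factors had a median of 0.0026 (adjusted p = 0.932), and the epidermal growth factor relative Ereg was at -0.34 ± 0.10 and Gas6 at 0.22 ± 0.06. The 34 p53 targets had a median of -0.03 (adjusted p = 0.760) and included Ei24 at 0.32 ± 0.06. The 27 targets of TGF-beta and YAP had a median of -0.0090 (adjusted p = 0.880), with Skil at -0.41 ± 0.19.

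Other signalling and metabolic lists did not pass in camera. The median was 0.0093 for 14 Notch genes (adjusted p = 0.713), with 0.20 ± 0.09 (SD, n = 4 mice) for Rbpj, and -0.04 for 31 genes of calcium handling and channels (adjusted p = 0.701), with -0.14 ± 0.09 for Orai1. It was 0.013 for 29 genes of the unfolded protein response (adjusted p = 0.932), where Sesn2 stood at -0.26 ± 0.13, 0.0079 for 18 heat shock genes (adjusted p = 0.863), where Cryab stood at -0.16 ± 0.04, and -7.63e-05 for 28 genes of glycolysis and hypoxia (adjusted p = 0.932), where Ero1a stood at 0.13 ± 0.03. Mean and median differed in sign for the unfolded protein, heat shock, growth factor, glycolysis, TGF-beta and striated muscle lists, all with an adjusted p of at least 0.863.

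Markers of other cell types did not move in one direction as lists. The camera adjusted p was 0.692 for endothelium (median -0.0090), 0.701 for leukocytes (0.05), 0.775 for adventitial fibroblasts (-0.0045) and 0.713 for cartilage and bone (-0.06). It was 0.511 for fat (0.06), 0.584 for nerve (-0.07), 0.917 for striated muscle (0.06) and 0.319 for mesothelium and epithelium (-0.06). Mixed fry, for differences in either direction, passed adventitial fibroblasts (adjusted p = 0.00883), fat (0.00883) and striated muscle (0.0172). The other lists of cell types did not pass in it. Single members differed: adjusted over the list alone, Sox9 (-0.50 ± 0.19, SD, n = 4 mice), the fibroblast matrix gene Dpt (-0.42 ± 0.10) and Lpl (-0.41 ± 0.18) passed on the lower side, and Cebpa (0.50 ± 0.19) and Lep (0.42 ± 0.20) on the higher side. With trend and robust set, Sox9 and Dpt passed, while Lpl, Cebpa and Lep did not (adjusted p = 0.0555, 0.158 and 0.264). Array signal was low for Lep (Ad-PL mean 2.76) and Cebpa (4.20). The alpha actin gene of skeletal muscle, Acta1, was at -0.52 ± 0.24 and passed with trend and robust set (adjusted p = 0.0378). Among the remaining lists that track sample quality, the 25 ribosomal protein genes had a median of 0.06 (adjusted p = 0.147), with Rps9 at 0.26 ± 0.03, and the 29 histone genes a median of 0.06 (adjusted p = 0.775), with H2bc14 at 0.43 ± 0.17. The array signal of H2bc14 was low (Ad-PL mean 1.99). The median level was 4.99 for the ribosomal protein list and 2.99 for the histone list, while Rps9 was brighter (Ad-PL mean 10.1).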

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

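The check for 1 mouse far from the others and the count of genes without the block over all splits of the samples were planned; the other tests in this part, which include the counts over splits with the block, were chosen after the results had been seen. Ivl, Kprp, Sprr2b, Mdm2, Cdkn1a, Ccng1, Gsn and Eng lie outside the rule for named genes and were chosen after the values were seen.

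In 5 of 170 genes and lists checked, the difference of 1 mouse stood far from those of the other 3, where about 8.5 would do so by chance. The urokinase receptor Plaur differed by 0.0684 in mouse 4 and by -0.38 to -0.37 in the others. The sterol reductase Dhcr7 differed by -0.0566 in mouse 3 against -0.30 to -0.27. Hexokinase 2, Hk2, differed by -0.083 in mouse 2 against -0.25 to -0.23. Lubricin, Prg4, differed by 0.451 in mouse 2 against 0.08 to 0.14. The histone gene H2bc15 differed by 1.11 in mouse 3 against 0.44 to 0.48.

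The first pattern weighed is the contrast between 2183 genes without the mouse as a block and 0 with it. Exchanging the groups within 1 to 3 mice weakens any difference common to the mice, yet the fit without the block called 154 to 1002 genes in the 7 such splits, and 288 to 435 in simulated data with no change, as a count inflated by removal of the mouse difference would. The 3 splits that part no pair called 0, which that removal fixes. The 24 that part 2 pairs also called 0, which the removal does not strictly fix. With the block, the real grouping gave 2291 genes at an unadjusted p under 0.05 against at most 1698 in the other splits, 131 against 0 with trend and robust set, and 10 gene lists against at most 5. In each case 1 of the 8 splits, the real one, reached that number, and 8 splits are too few for a share under 0.05.

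The second pattern is the joint lower level of the mitosis, interferon and contractile lists, with which the immediate-early genes, a sign of handling and serum response, were also lower (median -0.09, camera adjusted p = 0.00756, and adjusted p = 0.320 with an estimated correlation). Genes of similar level did not share this shift in the deposited values, since each of the 3 medians lay at least 0.0778 below the 1st percentile of 10000 random lists of matched level. That cannot decide whether such a shift existed before normalization, since quantile normalization makes the samples alike in distribution. The random lists also drew genes independently, and the 3 lists had been picked after they passed camera. Activation of p53 by Cre stays open: the p53 list had a median of -0.02901, with 6 members higher and 7 lower in 4 of 4 mice, and of its targets Mdm2 was higher in 4 of 4 (0.10 ± 0.04, SD), Cdkn1a stood at 0.03 ± 0.07, Ccng1 at -0.0035 ± 0.035, Ei24 (0.32) and Gadd45a (0.34) were higher and Sesn2 (-0.26) and Tap1 (-0.32) lower in 4 of 4. A lower share of smooth muscle cells cannot be told apart either. Of the 8 lists of other cell types 3 medians lay above 0 and 5 below (5 and 3 with median centring). The smallest camera adjusted p of these lists was 0.3188. Of their 122 genes, 69 lie above the median level in these cells, with Gsn at 10.9 and Eng at 10.5. The labels call every Ad-Cre sample a knockout and state neither whether the cells carry a form of Nfat5 that Cre can cut nor what Ad-PL carries, so loss of NFAT5, an effect of Cre, a difference between the viruses and, untested, handling may each account for the pattern.

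The third pattern is the lower level of Sprr1a (-1.40), Lce3d (-0.86), Crct1 (-0.81) and involucrin, Ivl (-0.74 ± 0.16, SD, n = 4 mice), neighbours in the epidermal differentiation cluster. A shift of the whole cluster is a candidate explanation: the 8 other cluster genes above the median level had a median of -0.1659, and 6 of the 8 had a mean below 0, while all 53 other cluster genes had a median of -0.05, 5 of them lower in 4 of 4 mice, with a median of 0.0054 in mouse 4. Among the 8, Kprp (-0.50 ± 0.19) and Sprr2b (-0.43 ± 0.14) were lower in 4 of 4 mice. The 8 genes together gave a limma camera p of 0.00594, and of 0.0653 with an estimated correlation, and the 53 genes gave 0.0417 and 0.0869, which leaves it open. The design names loss of NFAT5 as a biological explanation, and no test here sets it apart from an effect of Cre or of the viruses.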

How the results depend on the processing

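The leave-one-mouse-out fits with trend and robust set and the choice of the mouse as a replicate block for the reported values were made after the data had been seen; the other alternatives were planned. Without the replicate block 2183 genes passed (976 higher, 1207 lower) and 95 over 1.5-fold, with a random block (consensus correlation -0.99) 2149 and 95, with trend and robust set 131 and 36, and without genes under the 50th percentile of level 1 and 1 (Sprr1a); an unadjusted p gave 2291. Both fits without a fixed block count residual degrees of freedom that the values do not hold. Leaving out samples gave 0 to 2087 genes, and 0 to 167 over 1.5-fold, over fits with and without the block. With trend and robust set, 37, 18, 45 and 108 genes passed without mouse 1, 2, 3 and 4, of which 31, 13, 41 and 77 were among the 131. Quantile normalization, median centring, the 25th percentile filter, the probe set choices, array weights and adjusted p of 0.01 or 0.10 left the count at 0. Nfat5 was -0.52 with all samples, except -0.50 with median centring and -0.51 with array weights. It was past the threshold at -0.52 without the block, with the random block and with trend and robust set, and was -0.55 to -0.48 with samples left out; without mouse 2 its adjusted p was 0.0583 with trend and robust set. Of the single genes named by the rule, 101 passed without the block, 40 with the block and trend and robust set, and 0 with the block alone. The rule picked genes by their p without the block, so the first of these counts is raised by selection. Of the 10 gene lists, 0 passed with an estimated correlation and 4 by fry (lysosome higher; contractile, interferon and ribosome biogenesis lower). In its directional form fry passed 5 lists in all, the NFAT family being the other. It ended the calls of mitosis (adjusted p = 0.0622), tonicity (0.0622), cholesterol synthesis (0.0622), immediate-early genes (0.0618), Nrf2 targets (0.127) and adhesion (0.183). The mixed form of fry, which does not ask that members share a direction, passed 23 of the 33 lists. Without mouse 1, 2, 3 or 4 the lists past the threshold numbered 7, 7, 7 and 9. Ribosome biogenesis and lysosome were lost without any 1 mouse, immediate-early genes without mouse 1, adhesion without mouse 2 and cholesterol synthesis without mouse 3, while G1/S replication was gained without mouse 4 (adjusted p = 0.0114). The block changed no list count, with 10 past in either fit, and no named gene or list past the threshold in the reported fit or in an alternative changed its sign. The medians of 13 of the 33 lists, none of them past it, crossed 0 under at least 1 alternative, as did Nfatc2 among the 136 genes named by the rule. Among genes over 1.5-fold the balance turned, with 52 higher and 43 lower without the block and 16 and 20 with trend and robust set. Causes other than those named were not tested. Signal over background is not given in the table, so dim probe sets cannot be told from background.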

Other observations

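The genes in the next 2 paragraphs were chosen after their values were seen, from the 131 that passed with trend and robust set, and all tests below were chosen after the results were seen.

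Single genes are given here, and no group of them was tested. In Ad-Cre cells the guidance cue Sema3e differed by -0.73 ± 0.21 (SD, n = 4 mice), the serotonin receptor Htr1b by -0.71 ± 0.29 and the enkephalin precursor Penk by -0.57 ± 0.28. The neighbouring decoy receptor genes Tnfrsf22 (-0.60 ± 0.16) and Tnfrsf23 (-0.56 ± 0.08) were both lower, as was Calcrl, the receptor for calcitonin gene-related peptide and adrenomedullin (-0.43 ± 0.19). Of the sodium pump, the beta subunits Atp1b1 (-0.63 ± 0.34) and Atp1b3 (-0.27 ± 0.10) were lower. The gap junction gene Gja1, which codes for connexin 43, differed by -0.35 ± 0.16 and the fibronectin receptor subunit Itga5 by -0.35 ± 0.17. Beside the mitotic genes of the lists, the cyclins Ccnd1 (-0.26 ± 0.07) and Ccnd3 (-0.34 ± 0.10) of the G1 phase were lower. Genes of differentiated muscle outside the lists included Hspb6 (-0.30 ± 0.15) and Dmpk (-0.31 ± 0.03). Interferon-inducible genes outside the lists included Cmpk2 (-0.51 ± 0.21), Rnf213 (-0.41 ± 0.12), Gbp7 (-0.37 ± 0.07) and the double-stranded RNA sensor Tlr3 (-0.32 ± 0.13).

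On the higher side, the amino acid transporter Slc38a7 differed by 0.61 ± 0.11 (SD, n = 4 mice), the selenium enzyme Sephs2 by 0.57 ± 0.20 and Hdgfl3 by 0.60 ± 0.22. Heg1, a membrane receptor of endothelial junctions, was at 0.36 ± 0.16. The cysteine dioxygenase Cdo1, a step in taurine synthesis, was at 0.31 ± 0.11, while the taurine transporter Slc6a6 was at -0.27 ± 0.05. The cytokine Mif was at 0.22 ± 0.03.

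Across genes, the within-mouse differences of 2 mice correlated weakly, with Pearson's r between 0.0171 (mice 2 and 4) and 0.160 (mice 1 and 3); genes are not independent replicates. Mouse 2 had the lowest mean r with the others, 0.0356. Among the 723 unnamed probe sets 0 passed in limma with the block, 76 (10.5%) had an unadjusted p under 0.05 and 72 passed without the block.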
